A study of Mus musculus with 38 samples.

How the data were processed

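Bulk RNA sequencing of mouse medial prefrontal cortex was analysed from 38 libraries, each from a separate animal per the labels. Tissue was dissected from 1 mm coronal sections, total RNA was isolated with GenElute columns and treated with DNase on the column, and mRNA was purified from 400 ng of it, per the labels' protocols. Libraries were made with the NEBNext Ultra II Directional kit and sequenced on a NovaSeq instrument as 150-bp paired-end reads with 20 M planned per sample, per the labels' protocols. Reads were trimmed with fastp 0.23.2, aligned to GRCm39 with STAR 2.7.10b and counted with featureCounts, per the submitters' processing notes. The authors deposited raw counts per gene, whole numbers without normalization, for all 38 libraries. The annotation release and the strand setting of counting are not given in the sources used here, so counts of overlapping genes on opposite strands, and of near-identical gene copies such as ribosomal protein, hemoglobin and heat shock genes, carry that uncertainty.

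The table held 57010 gene IDs, of which 22462 had 0 counts in every library. A gene table gave symbols for 52029 IDs, and 4981 stayed without one. That table describes GRCm38 (GENCODE vM21), another build than the counts, and served only for symbols, transcript length and GC content. Groups were formed from the labels by sex, genotype and stress: male control NS (5), control CVS (6), mutant NS (3) and mutant CVS (4), and 5 female libraries in each of the same groups. The names of male and female animals come from separate series and the sexes may be separate cohorts, so levels were not compared across them. The labels give no pairing of replicates. The 74 pairs of replicates were checked for copies: their chi-square per degree of freedom ranged from 3.495 to 15.22, and 0 pairs were identical.

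Analyses were run in R 4.3.3 with edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and sva 3.50.0, and figures were drawn with Python 3.11.15 and matplotlib 3.10.9. For each sex a quasi-likelihood model of edgeR with 4 groups was fitted with robust dispersion, TMM normalization and filterByExpr (minimum count 10, minimum total count 15), which left 17212 genes in males and 16435 in females. The biological coefficient of variation was 0.0831 in males and 0.07157 in females. A model of all 38 libraries with 8 groups (17671 genes, 0.07765) tested the sex differences. P values were adjusted with the Benjamini-Hochberg procedure over all tested genes of a comparison, with a threshold of 0.05. CPM of named genes were computed within a sex, those given per library or pooled over all 38 libraries with TMM factors of all 38, and those of Xist, Ddx3y and hemoglobin from the raw totals.

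The comparisons were, in each sex, stress in controls, stress in mutants, genotype without stress, genotype under stress and the interaction of genotype and stress, and across the sexes the difference of the stress effect in controls, of the genotype effect without stress and of the interaction. Comparisons, gene lists, thresholds, naming rule and alternatives were chosen before the data were examined. The pooled genotype and pooled stress comparisons, averaged over the groups of the 8-group model, were added after the data were examined, as were leave-one-out runs of the gene lists and the alternatives of the pooled comparisons.

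The 29 gene lists covered immediate early genes, glucocorticoid-responsive genes, GABA-A receptor subunits, markers of somatostatin, other GABAergic and cortical glutamatergic neurons, glutamate receptors and the excitatory synapse, presynaptic vesicle genes, stress neuropeptides and monoamine receptors, cytosolic ribosomal proteins, translation factors, nuclear-encoded oxidative phosphorylation, mitochondrially encoded proteins, proteasome subunits, the unfolded protein response, heat shock proteins, circadian clock genes, inflammatory genes, myelin genes, and markers of oligodendrocyte precursors, astrocytes, microglia, endothelial cells, meningeal fibroblasts, choroid plexus, blood, striatum, olfactory bulb and sex. Lists with at least 3 tested members were tested with camera at a preset correlation between genes of 0.01, with p adjusted over the lists of a comparison. Alternatives were camera with an estimated correlation and fry. Members were also adjusted over the list alone.

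Genes were named by a rule: the 8 smallest p values in each direction past the threshold, up to 4 members of each described list, and always Sst, Fkbp5, Sgk1, Fos, Npas4, Bdnf and Crh. Predicted genes and IDs without a symbol were not named unless said. Some genes that the rule names, and tests of the position of called genes in the genome, are not reported here. Where 0 genes passed, 3 per direction were given as values that did not pass. For genes picked by p value, counts of libraries in the direction of an effect come from the same libraries and add no support. Likeness of effects was measured as the correlation of log2 fold changes across genes, set beside 100 simulations of unchanged groups that share libraries, 20 splits of the shared libraries, and relabelled libraries (10000 draws, or all relabellings where stated as exact). P values of the 7 correlations were adjusted together.

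Alternatives were RLE size factors, no low-count filter, DESeq2, limma voom with quality weights, 1 surrogate variable, only the 2 compared groups, all 38 libraries in one model, and each library left out in turn. For likeness they were a minimum mean CPM of 10 and rank correlation. Each comparison was repeated on up to 100 other splits of the same libraries. Correlations across libraries used 100000 permutations.

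The total count per library was 17.64 M to 27.51 M. Recovery was tested on simulated data drawn with the means, library sizes and dispersions of the real genes. In these data 200 genes were changed, and 30 further genes were shifted 1.1-fold. Of genes changed 1.25-fold, 28.4% were called with 4 against 3 libraries (male stress in mutants). With 5 against 5, 38.8% (female genotype under stress) to 56.7% (female genotype without stress) were called. For 2-fold changes 66.7% (male genotype without stress) to 90.9% (female stress in controls) were called. False calls outside both sets numbered 3 to 6 per comparison, and 0 of the 200 genes were called with the wrong sign. Genes were drawn independently, without the shared structure of the real libraries, where other splits gave up to 88 calls. Real comparisons can therefore hold more false calls and recover fewer changes than the simulation. Where a group held 3 libraries, changes below 1.5-fold were therefore missed more often than found (47.8% of those at 1.5-fold were called).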

Results

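Medial prefrontal cortex of 38 mice was profiled by bulk RNA sequencing. Control mice carried Cre recombinase under the somatostatin promoter (SSTCre). Mutant mice carried, in addition, a conditional allele on which this Cre acts in somatostatin neurons. Animals of both genotypes were left unstressed (NS) or were subjected to 21 days of chronic variable stress (CVS), and tissue was collected 24 hours after the final stressor, per the labels. The male groups held 5 control NS, 6 control CVS, 3 mutant NS and 4 mutant CVS mice, and each of the 4 female groups held 5 mice. Each mouse gave 1 library. The total count per library ranged from 17.64 M to 27.51 M (mean 21.06 ± 2.275 M, SD, n = 38), with 21.07 ± 1.724 M in the 18 males and 21.05 ± 2.723 M in the 20 females. Levels are given as CPM (counts per 1000000 counts) with their SD. Log2 fold changes are given with a standard error derived from the quasi-likelihood test. It is the absolute log2 fold change divided by the square root of the test's F statistic.

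The sex labels were checked first, and the genotype labels were taken as given. The genotype of 1 mutant library stays open, since its genes point both ways (male mutant CVS replicate 1, see the pooled genotype comparison). Xist, the RNA that coats the inactive X chromosome, averaged 356.5 ± 43.4 CPM in the 20 female libraries (lowest 282.1) and at most 0.1038 CPM in any of the 18 male libraries. Ddx3y, a helicase encoded on the Y chromosome, averaged 43.8 ± 3.03 CPM in males. It had 0 counts in all 20 female libraries, which allows up to 0.109 to 0.170 CPM depending on the library. Another Y-linked gene, Kdm5d, reached 0.03635 CPM in 1 female mutant CVS library. These limits cover counting error only.

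The sexes also differed in the share of counts taken by a few transcripts. The most abundant ID of the count table, ENSMUSG00000119584, for which the gene table gives no symbol, took 5.72 ± 1.02% of counts in females and 0.0913 ± 0.0799% in males. Transcripts of the mitochondrial genome took 3.63 ± 0.253% in females and 5.95 ± 0.403% in males. Within females, the share of the most abundant ID was 5.31% in control NS, 6.55% in control CVS, 4.80% in mutant NS and 6.22% in mutant CVS mice. Expression levels were not compared between the sexes for these reasons, and each sex had its own fit.

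Male controls addressed how chronic stress altered the cortex without the mutation (6 CVS against 5 NS). Doc2b, a calcium sensor for neurotransmitter release, fell from 23.3 ± 2.71 to 16.8 ± 1.84 CPM, a log2 fold change of −0.47 ± 0.0808. Cbs, the cystathionine β-synthase of the transsulfuration pathway, fell from 29.95 ± 0.992 to 24.3 ± 0.810 CPM (−0.30 ± 0.0530). Both were below the control NS mean in 6 of 6 CVS libraries, with an adjusted p of 0.0351 from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. They were the only genes past the threshold among 17212 tested, with 1272 genes at an unadjusted p under 0.05 where chance gives 861. DESeq2 called 23 genes and limma voom called 1. No gene was called without any 1 of control NS replicates 1, 2, 3 or 5 or of control CVS replicates 2, 3, 4 or 5.

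With the preset correlation, camera called clock genes higher and activity-regulated genes lower as lists in stressed male controls. Among 17 circadian clock genes, 10 had a positive and 7 a negative log2 fold change. No member passed over all genes, while 7 were higher and 1 was lower when adjusted over the list alone. Dbp, a clock output factor, stood at 78.4 ± 17.5 CPM in NS and 110.6 ± 13.7 in CVS libraries (0.50 ± 0.132), Ciart at 0.63 ± 0.138 and Per3 at 0.29 ± 0.0610, while Arntl, a core activator of the clock, stood at −0.25 ± 0.0765. The camera adjusted p of this list was 5.76e-05, and the adjusted p was 0.310 with an estimated correlation. Of 28 immediate early genes, which neuronal activity induces, 27 were negative and 1 was positive, with a median of −0.38. Examples are Egr2 at −1.07 ± 0.445, Fos at −0.73 ± 0.369 and Npas4 at −0.63 ± 0.318. Neither over all genes nor adjusted over the list alone did any pass. The list had a camera adjusted p of 6.75e-11, and an adjusted p of 0.351 with an estimated correlation.

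Vascular, glial and somatostatin neuron markers were among the other lists called in stressed male controls. Of 15 endothelial and pericyte markers, 13 were negative (median −0.12). Over all genes 0 passed, and 2 were lower adjusted over the list alone: Cldn5, a tight junction protein of brain vessels, at −0.39 ± 0.0794, and Kdr, a VEGF receptor, at −0.53 ± 0.116. The camera adjusted p was 1.45e-06, against an adjusted p of 0.310 with an estimated correlation. Of 12 somatostatin interneuron markers 11 were negative (median −0.068), with Nos1 at −0.24 ± 0.0925 and Sst itself at −0.02 ± 0.0546; 0 passed over all genes or adjusted over the list alone, and the camera adjusted p of 0.0171 became an adjusted p of 0.310 with an estimated correlation. Heat shock proteins (13 of 14 negative), microglia markers (14 of 16), astrocyte markers (13 of 14), ribosomal proteins (70 of 81), nuclear-encoded oxidative phosphorylation (65 of 74), unfolded protein response genes (12 of 17) and inflammatory genes (12 of 13) were lower with camera adjusted p from 1.55e-05 to 0.0480, and adjusted p from 0.310 to 0.795 with an estimated correlation. No member of these passed over all genes. Adjusted over the list alone, Olfml3 of the microglia markers and Gja1 of the astrocyte markers were lower. The glucocorticoid-induced Fkbp5 (0.23 ± 0.0960) and Sgk1 (0.16 ± 0.0687) were above the control NS mean in 6 of 6 libraries but did not pass over all genes (edgeR adjusted p 0.641 and 0.644).

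Male mutants addressed the same stress with the mutation (4 CVS against 3 NS). The smallest p values belonged to Saxo2 (0.82 ± 0.202), the mitochondrial folate enzyme Mthfd1l (0.33 ± 0.0920) and Rasal1 (0.22 ± 0.0623) among higher genes, and to the carbonic anhydrase-related Car8 (−0.62 ± 0.148), Htatip2 (−0.40 ± 0.104) and Kank3 (−0.36 ± 0.0953) among lower ones. None of these passed (edgeR adjusted p 0.9997 each). Of 17212 genes 0 were called by edgeR's quasi-likelihood test, with 581 at an unadjusted p under 0.05, below the 861 that chance gives. DESeq2 and limma voom also called 0, and a fit of the 2 groups alone called 6.

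Several lists were still called in male mutants. Of 81 ribosomal protein genes 72 were positive (median 0.062; Rpsa 0.22 ± 0.0839, Rps26 0.21 ± 0.0717), and of 17 circadian genes 13 were positive (median 0.13; Dbp 0.49 ± 0.168, Per2 0.34 ± 0.118, Ciart 0.50 ± 0.181). Heat shock proteins were negative in 11 of 14 (median −0.068; Hspa8 −0.22 ± 0.0728). Glucocorticoid-responsive genes (14 of 22 positive, with Nfkbia at 0.26 ± 0.106 and the metallothionein Mt1 at 0.27 ± 0.114), oxidative phosphorylation (60 of 74 positive) and proteasome subunits (27 of 37 positive) made up the rest. In these 6 lists 0 members passed over all genes and 0 adjusted over the list alone. Camera adjusted p ranged from 4.66e-07 to 0.0307, and the adjusted p was 0.588 for the circadian and heat shock lists and 0.853 for the other 4 with an estimated correlation.

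The genotype comparison without stress in males (3 mutant against 5 control) gave 3 genes. Ccng1, a cyclin induced by p53, rose from 78.5 ± 3.50 to 95.3 ± 3.33 CPM (0.28 ± 0.0519, adjusted p 0.0464). Rnf39, a RING finger protein, fell from 7.17 ± 1.09 to 3.70 ± 0.160 CPM (−0.95 ± 0.152, adjusted p 0.00691). The third, Gm12663, is a predicted gene outside the naming rule and was named after its values were seen; it stood at 0.00996 ± 0.0223 CPM in controls and 2.66 ± 0.448 CPM in mutants (adjusted p 0.00322). Each difference was present in 3 of 3 mutant libraries, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of 17212 genes, 1055 had an unadjusted p under 0.05, DESeq2 called 5 and limma voom called 0. No gene was called without control NS replicate 5, 1 without mutant NS replicate 1 or 3, and 6 without control NS replicate 4.

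Immediate early genes were called lower as a list in unstressed male mutants with the preset correlation, with 28 of 28 negative and a median of −0.60. Fos (−1.07 ± 0.470; 37.0 ± 12.5 CPM in controls, 17.5 ± 13.6 in mutants), the phosphatases Dusp5 (−0.76 ± 0.220) and Dusp6 (−0.66 ± 0.218), and Npas4 (−0.82 ± 0.398) are examples. None passed over all genes or adjusted over the list alone; the camera adjusted p was 1.03e-16, and the adjusted p was 0.622 with an estimated correlation. Myelin genes were negative in 19 of 20 (median −0.17; Mog −0.36 ± 0.164), astrocyte markers in 14 of 14 (median −0.10; the glutamate transporter Slc1a2 −0.16 ± 0.0496) and mitochondrially encoded proteins in 13 of 13 (median −0.083). For these 3 lists 0 members passed over all genes and 0 adjusted over the list alone; camera adjusted p was 2.84e-04, 3.41e-05 and 0.0334, and the adjusted p 0.792, 0.622 and 0.819 with an estimated correlation.

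Among the 12 tested GABA-A receptor subunits 11 were positive (median 0.044). None passed over all genes, and Gabrd, the δ subunit of extrasynaptic receptors, was higher adjusted over the list alone (0.20 ± 0.0640; 58.7 ± 2.79 to 67.5 ± 2.30 CPM). The list had a camera adjusted p of 0.0163 and an adjusted p of 0.6248 with an estimated correlation. Circadian genes (13 of 17 negative), microglia markers (12 of 16), endothelial markers (13 of 15), unfolded protein response genes (13 of 17) and oxidative phosphorylation (56 of 74) were lower with camera adjusted p from 1.18e-04 to 0.0364, and adjusted p from 0.622 to 0.877 with an estimated correlation. No member of these passed over all genes; adjusted over the list alone Per2, Ctss, Mfsd2a and Esam were lower. Of the 10 lists called for genotype without stress in males, immediate early genes kept their call in 8 of 8 leave-one-out runs, and the other 9 lost it without mutant NS replicate 3. Sst, the peptide that defines the neurons in which Cre is active, stood at 126.9 ± 6.38 CPM in controls and 152.5 ± 8.12 in mutants (0.27 ± 0.0652), above the control mean in 3 of 3 libraries, with an edgeR adjusted p of 0.535. Cdhr1, a cadherin abundant in the olfactory bulb, stood at 25.02 and 26.58 CPM in mutant NS replicates 2 and 3 and at 16.01 CPM in control CVS replicate 1, and between 1.74 and 5.35 CPM in the other libraries. Whether the dissections of these animals took in neighbouring tissue is open and bears on this comparison, although 6 of 8 olfactory bulb markers were negative in it (camera adjusted p 0.8095). It also bears on the other comparisons that hold these libraries. These are male stress in both genotypes, male genotype under stress, the male interaction, the sex differences and the pooled comparisons.

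Under stress, male mutants differed from male controls in 9 genes (4 against 6). Penk, the enkephalin precursor, fell from 35.3 ± 2.66 to 26.8 ± 1.30 CPM (−0.39 ± 0.0641, adjusted p 0.0101), and Aldh1a1, a retinoic acid-synthesising enzyme, from 18.4 ± 1.57 to 12.8 ± 1.84 CPM (−0.53 ± 0.0908, adjusted p 0.0126). Cpne9, a copine (−0.31 ± 0.0522), Golm1, a Golgi membrane protein (−0.37 ± 0.0698), Megf11 (−0.56 ± 0.108) and Igfn1 (−0.79 ± 0.135) also fell. Ccng1 rose from 76.5 ± 1.56 to 94.6 ± 6.63 CPM (0.31 ± 0.0459, adjusted p 0.00437), and Crym, a thyroid hormone-binding protein, from 77.4 ± 9.44 to 104.8 ± 8.16 CPM (0.44 ± 0.0783, adjusted p 0.0420). These 8 genes differed in the same direction in 4 of 4 mutant libraries, and the ninth, Gm12663, was higher in 3 of 4 (0.0561 ± 0.0477 against 1.46 ± 1.13 CPM), by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. DESeq2 called 27 genes and limma voom 1. The count was 1 without mutant CVS replicate 3 or 4, 2 without control CVS replicate 4, 4 without control CVS replicate 1, 3 or 5, and 5 without mutant CVS replicate 2. Crym and Igfn1 kept their call in 1 of 10 leave-one-out runs and Golm1 and Megf11 in 2 of 10, and Crym and Igfn1 also lost it with limma voom and with 1 surrogate variable.

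Ribosomal protein genes were positive in 80 of 81 members in this comparison (median 0.11; Rps26 0.22 ± 0.0600, Rpsa 0.25 ± 0.0702), and myelin genes were negative in 19 of 20 (median −0.19; Aspa −0.33 ± 0.143, Mog −0.31 ± 0.144). None of either list passed over all genes or adjusted over the list alone. Their camera adjusted p were 1.85e-19 and 1.14e-05, and the adjusted p was 0.768 for each with an estimated correlation. Oxidative phosphorylation (62 of 74 positive, with Ndufb7 higher adjusted over the list alone at 0.20 ± 0.0495), circadian genes (15 of 17 negative, 0 adjusted over the list alone) and astrocyte markers (12 of 14 negative, with S100b lower adjusted over the list alone at −0.18 ± 0.0560) had camera adjusted p of 9.77e-08, 0.00196 and 0.00196, and adjusted p of 0.777, 0.768 and 0.768 with an estimated correlation. No member of these passed over all genes. Sst stood at 0.21 ± 0.0578 (edgeR adjusted p 0.311).

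Whether stress acted differently in male mutants was tested as an interaction. The smallest p values belonged to Ndufb7, a subunit of complex I (0.30 ± 0.0751), Saxo2 (0.97 ± 0.254) and Rps26 (0.32 ± 0.0913) on the positive side and to the kinase Yes1 (−0.48 ± 0.120), Htatip2 (−0.52 ± 0.132) and Zc2hc1a (−0.29 ± 0.0725) on the negative side, none of which passed (edgeR adjusted p 0.995 each). The quasi-likelihood test of edgeR called 0 of 17212 genes, with 720 at an unadjusted p under 0.05, below the 861 that chance gives. DESeq2 and limma voom also called 0. Immediate early genes had positive interaction terms in 28 of 28 (median 0.32), ribosomal proteins in 73 of 81 (median 0.10) and oxidative phosphorylation in 67 of 74 (median 0.082). None passed over all genes, and Ndufb7 alone was higher adjusted over the list alone. Camera adjusted p were 4.38e-07, 6.82e-11 and 1.46e-09, with an adjusted p of 0.922 each with an estimated correlation. The interaction holds the same control NS libraries as the male stress and genotype comparisons in which immediate early genes were lower. High values in that group alone would give each of these calls, so they are not separate results.

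**Figure D1:**
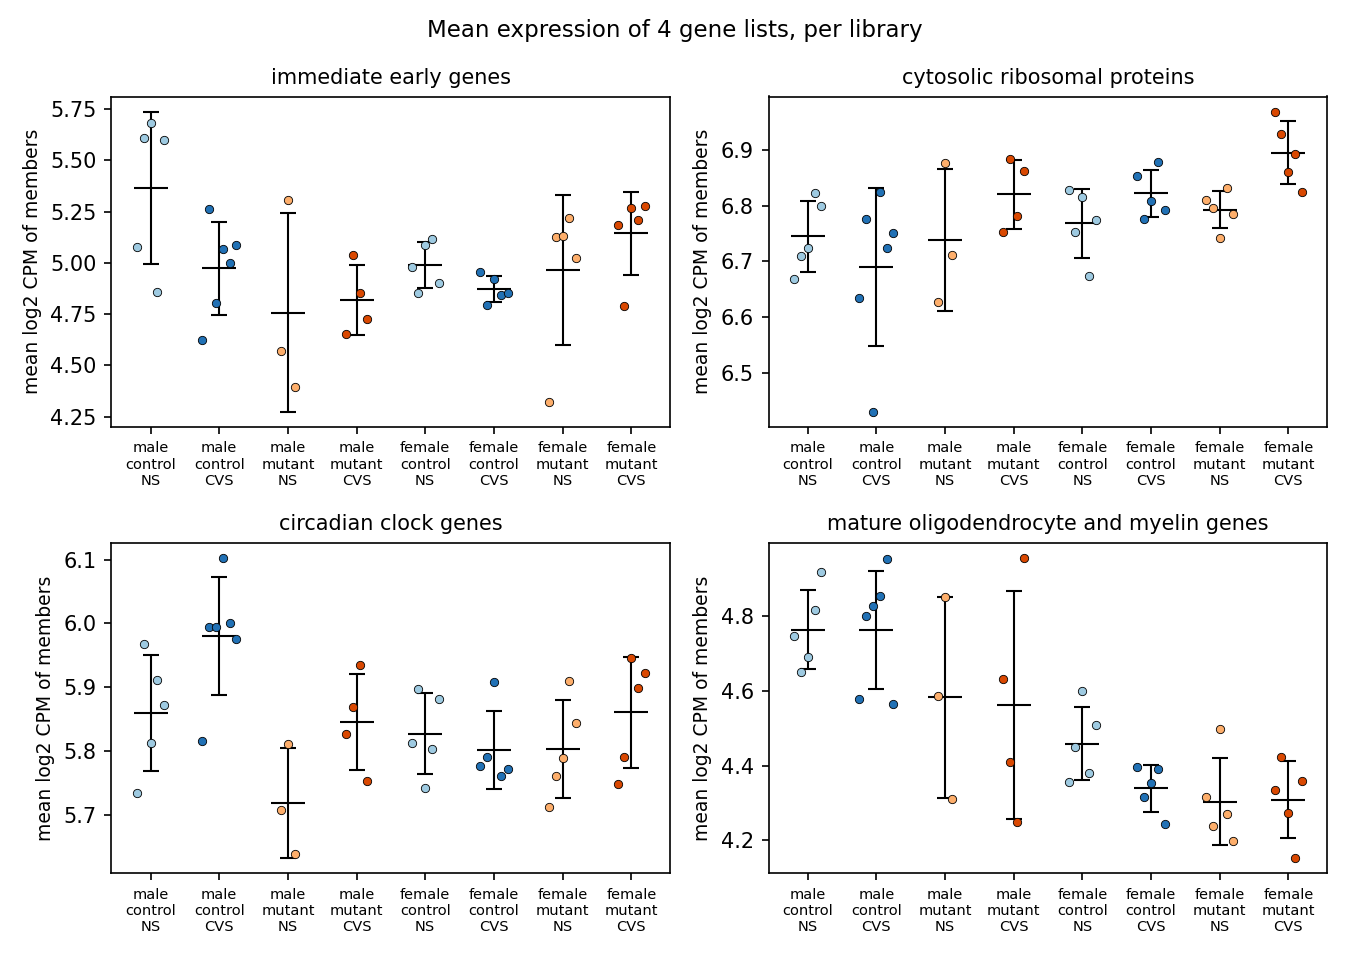
Mean log2 CPM of the members of 4 gene lists per library (points) with group mean ± SD; the vertical axes do not start at 0. Immediate early genes averaged 5.365 ± 0.373 in male control NS, 4.973 ± 0.227 in male control CVS and 4.757 ± 0.483 in male mutant NS libraries.

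Female controls addressed stress without the mutation (5 CVS against 5 NS). Tbc1d9b (0.26 ± 0.0483; 203.0 ± 5.60 to 242.9 ± 19.1 CPM), Ccdc74a (0.32 ± 0.0678) and the villin-like Vill (0.61 ± 0.131) had the smallest p values among higher genes, and the serine protease Htra1 (−0.21 ± 0.0459), the splicing factor Tra2b (−0.29 ± 0.0639) and the phosphatase Dusp14 (−0.26 ± 0.0565) among lower ones. None passed: the edgeR adjusted p was 0.107 for Tbc1d9b and 0.150 for the other 5. Each differed in the same direction in 5 of 5 libraries, which adds no support, since these genes were picked by p value from the same libraries. By edgeR's quasi-likelihood test 0 of 16435 genes were called, with 1433 at an unadjusted p under 0.05 where chance gives 822. DESeq2 called 28 genes, limma voom 0, and the edgeR fit without a low-count filter 51. The count rose to 9 without control CVS replicate 5 and to 6 without control CVS replicate 2.

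With the preset correlation, astrocyte and myelin lists were called lower in stressed female controls. Of 14 astrocyte markers 12 were negative (median −0.068). Over all genes 0 passed, and 2 were lower adjusted over the list alone: the water channel Aqp4 at −0.26 ± 0.0585 and the intermediate filament Gfap at −0.42 ± 0.127. Of 20 myelin genes 17 were negative (median −0.11). None passed over all genes, while Cldn11 (−0.21 ± 0.0639) and Ermn (−0.29 ± 0.0960) were lower adjusted over the list alone. Camera adjusted p were 1.67e-04 and 3.96e-04, and the adjusted p was 0.855 for both with an estimated correlation. Ribosomal proteins were positive in 71 of 80 (median 0.054; Rpl11 0.12 ± 0.0429), immediate early genes negative in 21 of 28 (median −0.16; Bdnf −0.27 ± 0.103) and endothelial markers negative in 11 of 15 (median −0.13). No member passed over all genes or adjusted over the list alone; camera adjusted p were 1.17e-08, 0.00987 and 0.0386, and the adjusted p 0.855, 0.872 and 0.872 with an estimated correlation. Outside the called lists, the peptides Npy (−0.30 ± 0.0704) and Cort (−0.76 ± 0.183) of the somatostatin interneuron markers were lower adjusted over the list alone, at edgeR adjusted p of 0.192 and 0.239 over all genes.

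In female mutants (5 CVS against 5 NS) ribosomal proteins were the list with the most members past a test. Of 80 tested, 77 were positive (median 0.11), 0 passed over all genes and 51 were higher adjusted over the list alone, such as Rpl13 (0.16 ± 0.0384; 244.0 ± 10.7 to 273.5 ± 13.7 CPM), Rps2 (0.16 ± 0.0383), Rps21 (0.20 ± 0.0483) and Rps14 (0.21 ± 0.0542). The camera adjusted p was 1.19e-35, and the adjusted p was 0.167 with an estimated correlation. The share of the most abundant ID was 1.425 points higher in CVS between these groups (exact permutation p 0.0159). Its link to this list was not tested. Meningeal fibroblast markers, which come from the covering of the brain, were negative in 11 of 12 (median −0.51; Ogn −0.96 ± 0.332, Col1a1 −0.75 ± 0.293), with 0 past over all genes and 0 adjusted over the list alone; camera gave an adjusted p of 2.66e-07, and the adjusted p was 0.547 with an estimated correlation. Tspan11 (−0.92 ± 0.170), Scai (−0.28 ± 0.0560) and Cd163, a scavenger receptor of perivascular macrophages (−1.19 ± 0.268), had the smallest p values among lower genes and Ddn, a dendritic protein (0.18 ± 0.0399), Sncb (0.15 ± 0.0337) and Kifc2 (0.16 ± 0.0371) among higher genes. None passed (smallest edgeR adjusted p 0.0694, Tspan11). By edgeR's quasi-likelihood test 0 of 16435 genes were called, with 1300 at an unadjusted p under 0.05, against 27 by DESeq2, 0 by limma voom and 36 by edgeR without a low-count filter. The count was 12 without mutant CVS replicate 5 and 4 without mutant NS replicate 1.

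Other lists were called in stressed female mutants. Immediate early genes were positive in 23 of 28 (median 0.15; Btg2 0.57 ± 0.245), oxidative phosphorylation in 64 of 74 (median 0.058; Ndufs7 0.17 ± 0.0433, higher adjusted over the list alone), mitochondrially encoded proteins in 12 of 12 (median 0.077) and microglia markers in 13 of 16 (median 0.044). Glucocorticoid-responsive genes were negative in 16 of 21 (median −0.10; Map3k6 −0.67 ± 0.182, lower adjusted over the list alone) and GABA-A receptor subunits in 10 of 12 (median −0.077). No other member passed adjusted over the list alone and none over all genes. Camera adjusted p ranged from 2.17e-09 to 0.0414, and adjusted p from 0.547 to 0.762 with an estimated correlation.

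Genotype without stress gave the most calls in females (5 mutant against 5 control). Vgf, the precursor of several neuropeptides, fell from 451.2 ± 20.9 to 335.8 ± 28.3 CPM (−0.43 ± 0.0476, adjusted p 4.08e-06) and Syt12, a synaptotagmin of synaptic vesicles, from 42.6 ± 2.73 to 32.9 ± 1.58 CPM (−0.37 ± 0.0554, adjusted p 4.12e-04). Ap1s1, a subunit of the AP-1 clathrin adaptor (−0.20 ± 0.0390), Ublcp1, a phosphatase acting on the proteasome (−0.34 ± 0.0670), Grin2c, an NMDA receptor subunit (−0.27 ± 0.0538), the potassium channel subunits Kcng4 (−1.03 ± 0.203) and Kcnj12 (−0.40 ± 0.0802), and Megf11 (−0.39 ± 0.0794) fell as well, each with an adjusted p of 0.0248. Among higher genes, Ccng1 rose from 71.3 ± 2.51 to 88.9 ± 6.57 CPM (0.32 ± 0.0516, adjusted p 0.00180). The nucleosome assembly protein Nap1l1 (0.17 ± 0.0351), the collagen VI chain Col6a2 (0.61 ± 0.118), the organic cation transporter Slc22a3 (0.96 ± 0.202), Tmem255a (0.49 ± 0.108) and the G protein subunit Gng4 (0.25 ± 0.0547) rose too. All of these were in the stated direction in 5 of 5 mutant libraries.

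In all, 21 of 16435 genes were called in unstressed females, 7 higher and 14 lower, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment; 1327 had an unadjusted p under 0.05, DESeq2 called 88 and limma voom 65. Gm12663, at 0.136 ± 0.167 CPM in controls and 2.45 ± 0.907 CPM in mutants, was among them. The count was 6 without mutant NS replicate 5 and 47 without control NS replicate 1, and between 8 and 12 without control NS replicates 2 to 5 or mutant NS replicate 3. With all 38 libraries in one fit 7 genes were called.

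Markers of inhibitory neurons other than somatostatin cells were called lower as a list in unstressed female mutants with the preset correlation. Of 16, 14 were negative (median −0.089). Over all genes 0 passed, and 5 were lower adjusted over the list alone: Pvalb (−0.49 ± 0.122; 31.8 ± 6.42 to 22.7 ± 3.38 CPM), Cck (−0.13 ± 0.0427), the vesicular GABA transporter Slc32a1 (−0.15 ± 0.0493), the GABA-synthesising enzyme Gad1 (−0.12 ± 0.0424) and Tac1 (−0.31 ± 0.121). The camera adjusted p was 4.09e-04, and the adjusted p was 0.163 with an estimated correlation; fry, which asks whether the members move one way on balance, gave an adjusted p of 0.0477. Striatal neuron markers had 8 of 12 negative, 1 higher and 3 lower adjusted over the list alone, a camera adjusted p of 0.178, an adjusted p of 0.6001 with an estimated correlation and the same fry adjusted p of 0.0477. Sst stood at 122.8 ± 12.1 CPM in controls and 134.3 ± 6.65 in mutants (0.13 ± 0.0645, edgeR adjusted p 0.629).

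Myelin genes were negative in 18 of 20 in this comparison (median −0.15; Mag −0.26 ± 0.0768 and Ppp1r14a −0.52 ± 0.167 lower adjusted over the list alone), astrocyte markers in 13 of 14 (median −0.076; S100b −0.21 ± 0.0496 lower adjusted over the list alone) and presynaptic vesicle genes in 13 of 19 (median −0.033; the complexins Cplx1 −0.21 ± 0.0551 and Cplx2 −0.12 ± 0.0383 lower adjusted over the list alone). Over all genes 0 passed. Camera adjusted p were 3.43e-06, 5.04e-05 and 0.0302, and the adjusted p 0.534, 0.564 and 0.633 with an estimated correlation. Meningeal markers were positive in 11 of 12 (median 0.33; Ogn 0.65 ± 0.325) and ribosomal proteins in 56 of 80, while oxidative phosphorylation (57 of 74), mitochondrially encoded proteins (11 of 12), microglia (14 of 16) and endothelial markers (13 of 15) were negative. Camera adjusted p of these 6 lists ranged from 7.01e-04 to 0.0302, and the adjusted p was 0.813 for ribosomal proteins and 0.633 for the others with an estimated correlation. No member passed over all genes, and adjusted over the list alone the 3 oxidative phosphorylation genes Ndufs7, Atp5g1 and Cox6a1 were lower.

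Under stress, female mutants differed from female controls in 4 genes (5 against 5). Ccng1 rose from 65.9 ± 5.00 to 86.1 ± 4.38 CPM (0.38 ± 0.0518, adjusted p 8.94e-05). Ublcp1 fell from 34.3 ± 1.40 to 26.5 ± 3.32 CPM (−0.38 ± 0.0673, adjusted p 0.0146) and Vgf from 416.1 ± 14.4 to 346.0 ± 23.3 CPM (−0.27 ± 0.0476, adjusted p 0.0167), and Gm12663 stood at 0.0521 ± 0.0550 against 2.32 ± 0.573 CPM. Each differed in 5 of 5 mutant libraries. The test was edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 16435 genes, of which 1164 had an unadjusted p under 0.05; DESeq2 called 14. The count was 2 without control CVS replicate 4 or 5 or mutant CVS replicate 1, 2 or 4.

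Immediate early genes were positive in 22 of 28 members in stressed female mutants (median 0.33; Sik1 0.53 ± 0.155, Egr1 0.33 ± 0.123, Fos 0.53 ± 0.247), ribosomal proteins in 76 of 80 (median 0.072; Rps27 0.18 ± 0.0510) and unfolded protein response genes in 16 of 16 (median 0.088; Atf4 0.19 ± 0.103). Circadian genes were positive in 13 of 17 (median 0.050), and presynaptic vesicle genes were negative in 15 of 19 (median −0.044; Cplx1 −0.16 ± 0.0550). None of these members passed over all genes or adjusted over the list alone. Camera adjusted p were 4.51e-08, 1.33e-19, 0.0160, 0.0331 and 0.0225, and the adjusted p was 0.914 for the circadian list and 0.672 for the other 4 with an estimated correlation.

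The interaction in females gave no gene past the threshold. Dmrta2 (0.80 ± 0.216), Syt12 (0.27 ± 0.0782) and the signalling inhibitor Spry4 (0.53 ± 0.151) had the smallest p values among positive terms and the coenzyme Q enzyme Coq3 (−0.41 ± 0.109), Col6a2 (−0.65 ± 0.167) and Khnyn (−0.34 ± 0.0956) among negative ones (edgeR adjusted p 0.9999 each). Of 16435 genes 0 were called by edgeR's quasi-likelihood test, with 658 at an unadjusted p under 0.05, below the 822 that chance gives. DESeq2 and limma voom also called 0, and edgeR without a low-count filter called 5. Astrocyte markers had positive terms in 14 of 14 (median 0.089; S100b 0.17 ± 0.0700), immediate early genes in 25 of 28 (median 0.30) and mitochondrially encoded proteins in 12 of 12 (median 0.11), while meningeal markers were negative in 11 of 12 (median −0.44). No member passed over all genes or adjusted over the list alone. Camera adjusted p were 1.62e-04, 2.95e-07, 0.00248 and 0.00385, and the adjusted p was 0.692 for each with an estimated correlation. The interaction shares the mutant NS libraries with stress in mutants and genotype without stress. The meningeal calls in these comparisons are therefore not separate results.

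Whether the sexes differed was tested on the effects, not on levels. The stress effect in controls differed most, by p value, in Mbnl2, a splicing regulator (male minus female 0.25 ± 0.0598), the calcium channel subunit Cacnb4 (0.27 ± 0.0661), Mthfd1l (0.45 ± 0.110), Gsta4 (−0.36 ± 0.0858), the stress-inducible Gadd45g (−0.76 ± 0.183) and Jund (−0.26 ± 0.0674), none of which passed (edgeR adjusted p 0.507, and 0.537 for Jund). By edgeR's quasi-likelihood test 0 of 17671 genes were called for the stress effect in controls, 0 for the genotype effect without stress and 0 for the interaction, with 1271, 728 and 571 genes at an unadjusted p under 0.05 where chance gives 884. DESeq2 and limma voom called 0 in each. For the genotype effect the smallest p values belonged to Plxdc1 (0.60 ± 0.151), Cbln3 (3.74 ± 0.922) and Cnpy1 (5.84 ± 1.48) on the positive side and to Faap100 (−0.62 ± 0.157), Rpain (−0.55 ± 0.154) and Galnt3 (−1.18 ± 0.351) on the negative side; for the interaction they belonged to Chtf18 (1.36 ± 0.401), Faap100 (0.71 ± 0.213), Asb3 (0.58 ± 0.175), Ddt (−1.01 ± 0.252), Megf11 (−0.69 ± 0.194) and Cbln3 (−5.005 ± 1.39).

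Some lists differed between the sexes with the preset correlation. In the stress effect of controls, circadian genes were more positive in males in 14 of 17 (median 0.22; Ciart 0.65 ± 0.217, Hlf 0.28 ± 0.0810 and Nr1d2 0.34 ± 0.0978 adjusted over the list alone) and ribosomal proteins more negative in 78 of 82 (median −0.10). Immediate early genes were more negative in males in 21 of 28 for this effect (median −0.26) and in 27 of 28 for the genotype effect without stress (median −0.57). No member passed over all genes, and apart from the 3 clock genes none of these lists had a member past the test adjusted over the list alone. Camera adjusted p were 5.09e-05, 2.34e-11, 0.00178 and 2.65e-12, and the adjusted p 0.957, 0.996, 0.996 and 0.949 with an estimated correlation.

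Across the 10 comparisons within a sex and the 3 sex differences, camera with its preset correlation made 90 list calls, and 0 of them held with an estimated correlation. Calls of the same list in comparisons that share a group are not independent. Among the 29 lists, 10 were called in no comparison within a sex that tested them, which were 10 comparisons for 8 of them and the 5 male ones for choroid plexus markers and sex-linked genes: cortical glutamatergic neuron markers (smallest camera adjusted p 0.0799), glutamate receptors and excitatory synapse genes (0.0749), stress neuropeptides and monoamine receptors (0.237), translation factors (0.186), oligodendrocyte precursor markers (0.0577), choroid plexus markers (0.435), blood cell markers (0.0547), striatal neuron markers (0.178), olfactory bulb markers (0.341) and sex-linked genes (0.157). Their adjusted p was 0.6001 or more with an estimated correlation.

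Whether mutants without stress resembled stressed controls was asked by correlating log2 fold changes across genes, which are not independent replicates. In males r was 0.418 (rho 0.416) over 17212 genes. Both comparisons share the control NS libraries, and simulated unchanged groups gave a mean r of 0.443; relabelled libraries gave 0.342 to 0.553 in their central 95% (permutation p 0.532, two-sided). The covariance was 0.0180 beside a simulated 0.0171. With the control NS libraries split between the comparisons, r averaged 0.0305. In females r was 0.397 (rho 0.316) over 16435 genes against a simulated 0.4928 and a relabelled range of 0.404 to 0.589 (permutation p 0.0294, adjusted 0.103), the covariance was 0.01373 beside 0.01405, and r with split controls averaged −0.0213.

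Whether both genotypes responded alike to stress was asked in the same way, with no shared libraries. In females r was 0.131 (rho 0.188, relabelled range −0.110 to 0.110, exact permutation p 0.0209, two-sided). The covariance was 0.004308 beside a simulated 3.4e-05 and a relabelled range of −0.003493 to 0.003493. Genes at an unadjusted p under 0.05 in both overlapped in 193 cases in the same direction against 56.8 for independent lists, and in 15 in opposite directions against 56.6. In males r was −0.0140 (rho 0.0120, relabelled range −0.134 to 0.133, exact permutation p 0.831). The covariance was −5.96e-04 beside a simulated 1.69e-04 and a relabelled range of −0.005856 to 0.005815. Overlaps held 51 genes in the same direction against 21.4 and 18 in opposite directions against 21.5. The simulation and the counts for independent lists treat genes as independent, so an excess over either is no test of likeness. Adjusted over the 7 correlations of this family, p was 0.103 in females and 0.831 in males. Without 1 library the female r ranged from 0.0809 to 0.142, and over genes with a mean CPM of at least 10, for which no range was relabelled, it was 0.261. Stress effects in controls correlated between the sexes at r = 0.0855 (rho 0.0881; 16333 genes; relabelled range −0.0957 to 0.0957, exact permutation p 0.0780, adjusted 0.182).

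The stress effect in mutants and the genotype effect without stress share the mutant NS libraries, with opposite sign. Their r was −0.581 in males (rho −0.446; simulated −0.603; relabelled range −0.673 to −0.509; permutation p 0.722, adjusted 0.831) and −0.456 in females (rho −0.431; simulated −0.507; range −0.574 to −0.418; permutation p 0.286, adjusted 0.501). Covariances were −0.0312 beside a simulated −0.0298 in males and −0.0157 beside −0.0146 in females. With mutant NS libraries split, the female r averaged −0.0336; the 3 male libraries were too few to split.

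**Figure D2:**
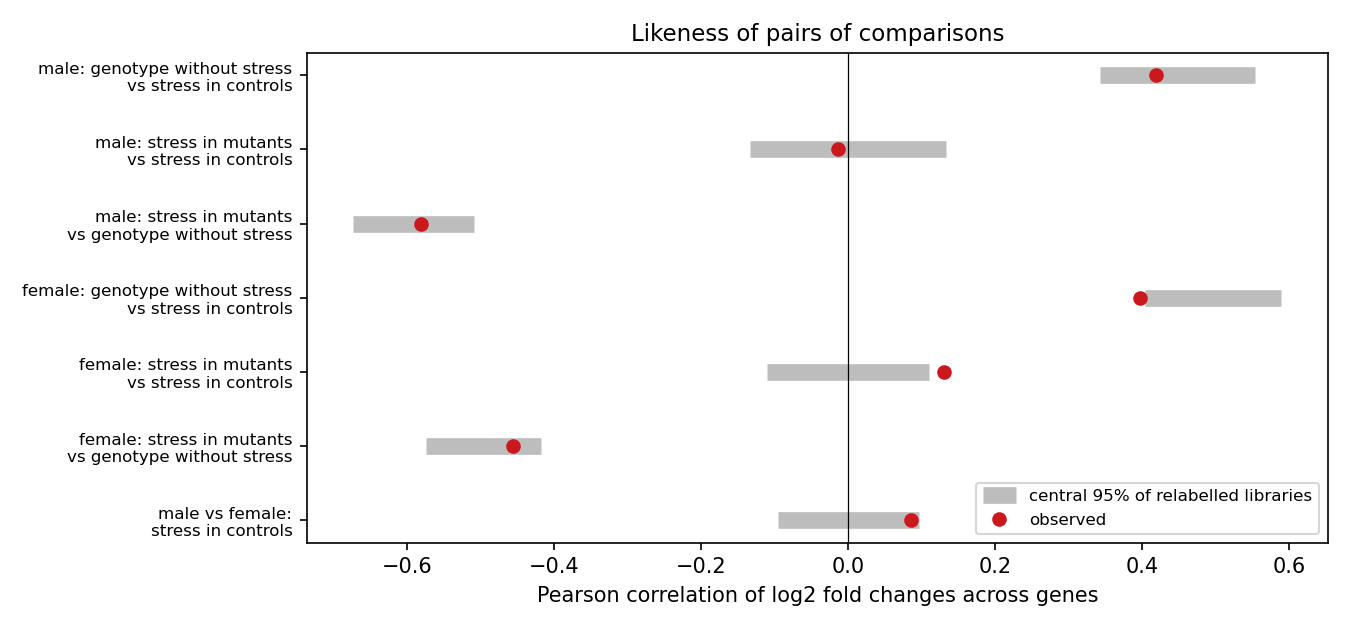
Pearson correlation of log2 fold changes across genes for 7 pairs of comparisons (points), with the central 95% of values from relabelled libraries (bars). The female stress effects of both genotypes (0.131) and the female genotype and stress effects (0.397) lie outside their ranges of −0.110 to 0.110 and 0.404 to 0.589.

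After the data were examined, genotype was also tested over both sexes and both stress conditions in one fit of 38 libraries (17 mutant against 21 control), since the calls within sexes were few. Ccng1 rose by 0.32 ± 0.0255 (90.8 ± 5.26 against 72.8 ± 4.31 CPM, adjusted p 3.76e-13), and Ublcp1 fell by 0.36 ± 0.0401 (27.6 ± 3.04 against 35.4 ± 2.29 CPM, adjusted p 3.45e-08). Gpr83, a G protein-coupled receptor, fell by 0.27 ± 0.0325, Vgf by 0.33 ± 0.0425 (352.2 ± 26.9 against 442.4 ± 43.2 CPM), and the serine protease Prss23 by 0.32 ± 0.0470. Set against the control mean of the same sex and stress condition, as for all library counts of this comparison, all 5 differed in the same direction in 17 of 17 mutant libraries. Rnf39 (−0.50 ± 0.0713), Cpne9 (−0.18 ± 0.0277), Megf11 (−0.31 ± 0.0486) and Syt12 (−0.20 ± 0.0324) fell in 16 of 17. On the other side Gng4 (0.20 ± 0.0303), the procollagen peptidase Adamts2 (0.40 ± 0.0636), the kinase Pnck (0.18 ± 0.0290), Thg1l, a tRNA-histidine guanylyltransferase (0.45 ± 0.0738), Lcorl (0.23 ± 0.0396), Ehbp1 (0.14 ± 0.0253) and Slc22a3 (0.55 ± 0.101) rose in 15 to 17 of 17. These tests used edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

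Some list members were past the threshold over all genes in the pooled genotype comparison. Sst rose by 0.19 ± 0.0336 (141.1 ± 10.6 against 124.5 ± 8.82 CPM; adjusted p 0.00143; 16 of 17 libraries), while Penk fell by 0.24 ± 0.0453 (adjusted p 0.00234; 15 of 17) and Tac1, the substance P precursor, by 0.27 ± 0.0646 (adjusted p 0.0211). The astrocyte genes S100b (−0.15 ± 0.0275), Slc1a2 (−0.096 ± 0.0244) and the pump subunit Atp1b2 (−0.078 ± 0.0210) fell, as did Grin2c (−0.16 ± 0.0306), by edgeR's quasi-likelihood test. Without 1 library at a time S100b kept its call in 38 of 38 runs, Slc1a2 in 23 and Atp1b2 in 13. In total 193 of 17671 genes were called, 60 higher and 133 lower, with 1981 at an unadjusted p under 0.05. DESeq2 called 299 genes, and the count was 101 without male mutant NS replicate 3, a library with high Cdhr1. Pttg1, the securin of chromosome separation, fell from 18.7 ± 1.22 CPM in controls, with a single mutant library at their level: 11 of 17 mutants lay under 1 CPM, 5 between 7.94 and 10.5 CPM, and male mutant CVS replicate 1 at 18.7 CPM. That library was inside the control range for Ublcp1 (33.55 CPM, controls 31.91 to 41.87) and Gm12663 (0 counts). It was above that range for Ccng1 (91.63 CPM, controls 62.45 to 79.99). As in every mutant library, Gpr83, Vgf and Prss23, like Ublcp1, were below the mean of its matched controls. Their calls include this library, so this adds no support for its label. Vgf, scaled within males, was 358.6 CPM in it, inside the male control CVS range of 350.8 to 524.4 CPM. By the control range, Pttg1, Ublcp1 and Gm12663 point one way and Ccng1 the other, so its genotype stays open. The library was kept as a mutant throughout. Without it 156 genes were called for pooled genotype and 6 for male genotype under stress.

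Camera with its preset correlation called 9 lists in the pooled genotype comparison. Of 14 astrocyte markers 14 were negative (median −0.061), 3 were lower over all genes and 5 adjusted over the list alone. Myelin genes were negative in 20 of 20 (median −0.14), with 0 over all genes and 1, Mog (−0.24 ± 0.0679), adjusted over the list alone. Ribosomal proteins were positive in 80 of 82 (median 0.050), with 0 over all genes and 10 adjusted over the list alone, such as Rps15a (0.076 ± 0.0228) and Rpl10 (0.071 ± 0.0222). Endothelial markers were negative in 15 of 15 (median −0.088), with 0 over all genes and 3 adjusted over the list alone. Camera adjusted p were 3.91e-07, 3.30e-10, 1.34e-16 and 0.001165, and the adjusted p was 0.472 for each with an estimated correlation. Immediate early genes (23 of 28 negative), microglia markers (15 of 16), circadian genes (15 of 17), oligodendrocyte precursor markers (8 of 11) and other GABAergic markers (11 of 16) were called lower as well, with camera adjusted p of 2.00e-04, 2.61e-04, 0.00963, 0.00963 and 0.0225. With an estimated correlation the adjusted p was 0.579 for immediate early genes and 0.472 for the other 4. Over all genes Tac1 alone of these members passed; adjusted over the list alone 0, 0, 2, 3 and 2 were lower.

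**Figure D3:**
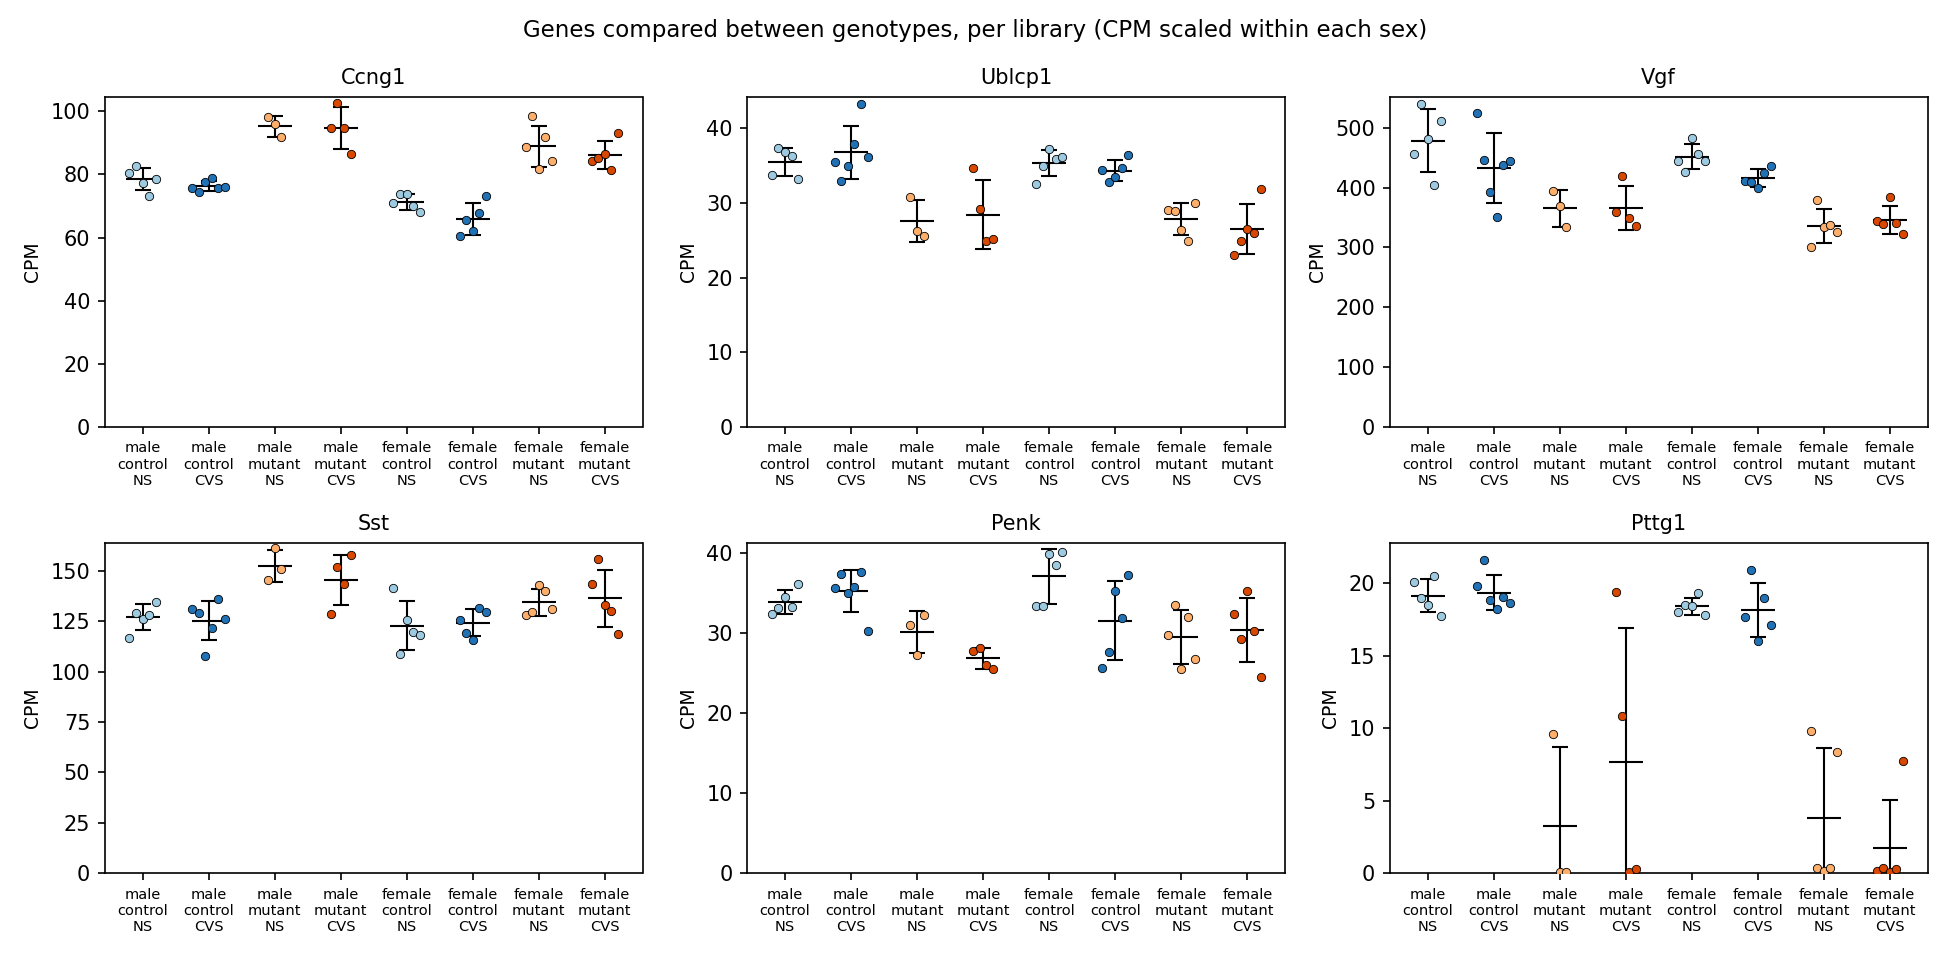
CPM of 6 genes per library (points), scaled within each sex, with group mean ± SD. Ccng1 averages 88.9 CPM in female mutant NS against 71.3 in female control NS libraries, Vgf 335.8 against 451.2, and Pttg1 divides the mutant libraries into 11 under 1 CPM, 5 at 7.73 to 10.8 CPM and 1 at 19.4 CPM.

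Stress was pooled in the same way after the data were examined (20 CVS against 18 NS). Dbp rose by 0.35 ± 0.0628 (108.3 ± 11.6 against 87.3 ± 17.1 CPM; 19 of 20 libraries, set against the NS mean of the same sex and genotype). Colq, the collagen tail of acetylcholinesterase, fell by 0.72 ± 0.139 (1.20 against 1.99 CPM; 20 of 20) and Htra1 by 0.14 ± 0.0278 (135.4 against 150.6 CPM; 20 of 20). These 3 genes, each at an adjusted p of 0.0406 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, were the calls among 17671 genes, with 1655 at an unadjusted p under 0.05; DESeq2 called 35 and limma voom 0. Leaving out 1 library at a time gave between 0 and 16 calls, and Dbp, Colq and Htra1 all lost their call with limma voom and with 1 surrogate variable.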

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

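All tests below of what lies behind a pattern were chosen after the result was seen, except those on other splits of the same libraries.

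In groups of 4 to 10 libraries, single libraries were marked where their gap to the others was larger than Dixon's test allows at 95%. Chance marks about 1 in 20 groups: 159 groups were tested, 7.95 are expected and 8 were found, so no pattern is read into them. Fkbp5 (52.45 CPM) and Sgk1 (56.49 CPM), both glucocorticoid-induced, were marked in female control CVS replicate 2, and Bdnf in female control NS replicate 3 (51.63 CPM). Penk was marked in male control CVS replicate 6 (29.3 CPM) and Gm12663 in male control NS replicate 5 (0.04793 CPM). The other 3 were the total count of female mutant CVS replicate 4 (27.51 M), the share of the most abundant ID in male control CVS replicate 5 (0.4058%) and hemoglobin in male control NS replicate 4 (172.9 CPM).

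The other 30 marks are gene lists whose effect differed between genotypes or sexes by camera with its preset correlation; 0 of them did so with an estimated correlation. Values are median log2 terms. In the male interaction these were immediate early genes (0.318), GABA-A receptor subunits (−0.06473), ribosomal proteins (0.1041), oxidative phosphorylation (0.08158), proteasome subunits (0.04492), inflammatory genes (0.2321), microglia markers (0.0498) and endothelial markers (0.1076). In the female interaction they were immediate early genes (0.3036), glucocorticoid-responsive genes (−0.1343), other GABAergic markers (0.07385), ribosomal proteins (0.05631), oxidative phosphorylation (0.05692), mitochondrially encoded proteins (0.1096), unfolded protein response genes (0.08464), circadian genes (0.07092), myelin genes (0.1002), astrocyte markers (0.08871), endothelial markers (0.1327) and meningeal markers (−0.442). Between the sexes, the stress effect in controls differed for immediate early genes (−0.2594), GABA-A receptor subunits (0.05923), ribosomal proteins (−0.104), oxidative phosphorylation (−0.06048), circadian genes (0.2187) and microglia markers (−0.121). The genotype effect without stress differed for immediate early genes (−0.5741) and circadian genes (−0.05463), and the interaction for ribosomal proteins (0.05813) and oxidative phosphorylation (0.02882).

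Camera with its preset correlation called immediate early genes lower as a list in male control CVS and in male mutant NS than in male control NS libraries, but not with an estimated correlation (adjusted p 0.351 and 0.622), and no member passed over all genes or adjusted over the list alone. Chance differences between libraries stay open, since the mean log2 CPM of the list gave an exact permutation p of 0.0671 between control NS and control CVS (462 splits) and 0.107 between control NS and mutant NS (56 splits). A single high control NS library is argued against: without each in turn the median log2 fold change was at most −0.3031. Library size cannot be told apart from no such influence: over 18 males r was 0.190 (permutation p 0.4505), rho 0.348 (permutation p 0.157) and r 0.340 without the 2 farthest libraries, but control NS totals were 1.21 M above control CVS (exact p 0.323). No biological explanation was tested.

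Female stress effects in both genotypes correlated at 0.131. The share of the most abundant ID is argued against, since r was 0.1558 with that share as a covariate in each genotype (relabelled range −0.1147 to 0.1147), although the share was higher in CVS by 1.239 points in controls (exact p 0.0952) and 1.425 in mutants (exact p 0.0159). Gene length and GC content cannot be told apart from a shared response, since r went from 0.1324 to 0.1129 with both removed, just above a relabelled range of −0.1114 to 0.1114. Chance stays open, with an exact p of 0.1029 adjusted over 7 correlations; r was 0.261 over genes with a mean CPM of at least 10, for which no range was relabelled. No biological explanation was tested.

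Other splits of the same libraries show whether chance can give the number of calls. Fewer than 5% of splits gave as many calls for male stress in controls (2 genes, 3 of 100 splits, highest 3) and female genotype without stress (21, 2 of 100, highest 42). The same held for pooled genotype (193, 1 of 100, highest of the others 14) and pooled stress (3, 1 of 100, highest of the others 1). The count of splits includes the real one. These shares rest on at most 100 splits and were not adjusted over the 15 comparisons. They do not exclude chance by themselves, although the 193 pooled genotype calls lay far above 14. At least 5% of splits gave as many for male genotype without stress (3, 4 of 56, highest 24) and under stress (9, 7 of 100, highest 88). The same held for female genotype under stress (4, 6 of 100, highest 34). With 0 genes called, every split gave as many: male stress in mutants (35 of 35, highest 1), male interaction (100 of 100, highest 8), female stress in controls (100 of 100, highest 6), female stress in mutants (100 of 100, highest 65), female interaction (100 of 100, highest 1), and the sex differences of stress (100 of 100, highest 1), genotype (100 of 100, highest 34) and interaction (100 of 100, highest 1). Splits with 88, 65, 42, 34 and 24 genes point to a structure of the samples, whose cause was not tested.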

How the results depend on the processing

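The alternatives of the pooled comparisons and the leave-one-out runs of gene lists were tests chosen only after the result was seen. RLE size factors left every count within 1.5 times its value. Without a low-count filter edgeR called 15 genes for male stress in controls, 11 and 43 for male genotype without and under stress, 51 and 36 for female stress in controls and mutants, 118 and 23 for female genotype without and under stress, 5 for the female interaction and 6 for pooled stress. DESeq2 called 23, 5 and 27 for the same male comparisons, 28 and 27 for female stress in controls and mutants, 88 and 14 for female genotype without and under stress, 299 for pooled genotype and 35 for pooled stress, of which 2 were among the 3 of edgeR. Limma voom called 1 for male stress in controls, 0 and 1 for male genotype without and under stress, 65 for female genotype without stress and 0 for pooled stress. With only the 2 compared groups, counts were 4 and 6 for male stress in controls and mutants and 2 and 5 for female stress. With all 38 libraries they were 0 for male stress in controls and 7 and 2 for female genotype without and under stress. With 1 surrogate variable pooled stress gave 1 gene, and Dbp, Colq and Htra1 were all lost. Of the 90 list calls 0 held with an estimated correlation, and fry called 2 lists, of which other GABAergic markers were among the 90 and striatal markers were not.

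For likeness over genes with a mean CPM of at least 10, r was 0.0591 for male stress in both genotypes, −0.440 for male stress in mutants and genotype, 0.260 for female genotype and stress, 0.261 for female stress in both genotypes, −0.380 for female stress in mutants and genotype and 0.1305 for stress in controls of both sexes. Rank correlation gave −0.446 for male stress in mutants and genotype, 0.316 for female genotype and stress and 0.188 for female stress in both genotypes. Without 1 library r ranged from 0.324 to 0.507 (male genotype and stress), −0.688 to −0.523 (male stress in mutants and genotype), 0.357 to 0.476 (female genotype and stress), −0.524 to −0.409 (female stress in mutants and genotype), −0.0790 to 0.0440 (male stress in both genotypes), 0.0530 to 0.107 (stress in controls of both sexes, lowest without female control NS replicate 3) and 0.0809 to 0.142 (female stress in both genotypes). The last fell by more than 1.5 times without female control CVS replicate 1 (0.0809) or mutant NS replicate 2 (0.0844), and was inside the range of −0.110 to 0.110, which was relabelled with all libraries, without these and others.

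Counts without 1 library ranged from 0 to 3 for male stress in controls, 0 to 6 and 1 to 12 for male genotype without and under stress, 0 to 9 and 0 to 12 for female stress in controls and mutants, 6 to 47 and 2 to 5 for female genotype without and under stress, 101 to 233 for pooled genotype and 0 to 16 for pooled stress. The libraries that moved a count most were male control NS replicate 5 (0 calls for male genotype without stress), male mutant CVS replicates 3 and 4 (1 call each under stress), female control NS replicate 1 (47) and mutant NS replicate 5 (6), male mutant NS replicate 3 (101 for pooled genotype) and female mutant NS replicate 1 (16 for pooled stress). The cause was not tested. Ccng1 kept its call without each library in turn in both female comparisons and in males under stress, as did Vgf and Syt12 in unstressed females, but in unstressed males Ccng1 kept it in 1 of 8 runs and lost it with limma voom. For male genotype under stress Crym and Igfn1 kept their call in 1 of 10 runs and lost it with limma voom and 1 surrogate variable, Igfn1 also without a low-count filter, and Golm1 and Megf11 kept it in 2 of 10 and lost it with limma voom. In unstressed females Col6a2 and Tmem255a kept their call in 2 of 10 runs, Gng4 in 3, Nap1l1 and Slc22a3 in 4, Ublcp1, Grin2c, Kcng4, Kcnj12 and Megf11 in 5 and Ap1s1 in 6. Under stress in females Ublcp1 kept its call in 5 of 10 runs and Vgf in 4 of 10. In the pooled genotype comparison Slc1a2 kept it in 23 of 38 runs and lost it without a low-count filter, and Atp1b2 kept it in 13 of 38 and lost it without a filter and with RLE size factors. Doc2b lost its call with limma voom and in 8 of 11 leave-one-out runs, Cbs in 10 of 11, and Rnf39 with limma voom and without male control NS replicate 5 or mutant NS replicate 1 or 3. For male genotype without stress 9 of the 10 called lists lost their call without mutant NS replicate 3, and immediate early genes kept it in every run. Other lists often lost a call too: unfolded protein response genes kept it in 4 of 11 runs and inflammatory genes in 5 of 11 (male stress in controls), glucocorticoid-responsive genes and proteasome subunits in 3 of 7 (male stress in mutants), inflammatory genes in 7 of 18 (male interaction), endothelial markers in 4 of 10 (female stress in controls) and 9 of 20 (female interaction), microglia markers in 5 of 10 (female stress in mutants), mitochondrially encoded proteins in 4 of 10 (female genotype without stress), circadian genes in 4 of 10 (under stress) and oxidative phosphorylation in 18 of 38 (sex difference of the interaction). With 1 surrogate variable calls were lost for unfolded protein response genes (male stress in controls and genotype without stress), oxidative phosphorylation (male genotype without stress and pooled stress), mitochondrially encoded proteins (male genotype without stress), microglia markers (female stress in mutants), and GABA-A receptor subunits and meningeal markers (pooled stress). Over all named genes and alternatives 15777 results stayed the same, 439 were weaker, 169 stronger and 0 reversed. Over lists these numbers were 8630, 480, 213 and 0. Results called in neither fit count as the same, whatever their sign. A reversal was counted only for called genes and for lists called in both fits. These totals therefore do not measure how often a call was kept.

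No paired analysis was possible because the labels give no pairing of replicates. With 3 or 4 mutants per male group, 28.4% of genes with the smallest simulated change were called for male stress in mutants, so a count of 0 there leaves small changes open.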

Other observations

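Lists of heat shock and clock genes were among the 11 called in the pooled stress comparison (20 CVS against 18 NS libraries). Within a sex both were called for stress in male controls and male mutants, with adjusted p of 0.310 and 0.588 with an estimated correlation; in females the camera adjusted p was 0.691 in controls and 0.437 in mutants for heat shock proteins and 0.191 and 0.166 for clock genes. The difference between the sexes of the stress effect in controls was not called for heat shock proteins (camera adjusted p 0.0623); for clock genes it was called at 5.09e-05, and the adjusted p was 0.957 with an estimated correlation. Of 14 heat shock proteins 12 were negative (median −0.053). None passed over all genes and 6 were lower adjusted over the list alone, such as the chaperones Hspa8 (−0.092 ± 0.0295; 1424 ± 84.2 against 1508 ± 110 CPM), Hspa4 (−0.066 ± 0.0204) and Dnaja1 (−0.070 ± 0.0229). The camera adjusted p was 8.12e-05, and the adjusted p was 0.354 with an estimated correlation. Of 17 circadian genes 11 were positive and 6 negative (median 0.054), 1 was higher over all genes (Dbp), and 8 were higher and 2 lower adjusted over the list alone. Ciart stood at 0.35 ± 0.0834, Nr1d1 at 0.18 ± 0.0526 and Clock at −0.075 ± 0.0244; the camera adjusted p was 8.12e-05 and the adjusted p 0.354 with an estimated correlation. Time of day of dissection is not given in the sources used here.

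Somatostatin interneuron and glial lists were called in the same comparison. Npy, of the somatostatin interneuron markers (10 of 12 negative, median −0.053), stood at −0.15 ± 0.0365 and was the 1 member lower adjusted over the list alone, with 0 over all genes; the camera adjusted p was 0.00307 and the adjusted p 0.354 with an estimated correlation. Oligodendrocyte precursor markers were negative in 11 of 11 (median −0.055), with Gpr17 (−0.16 ± 0.0471) lower adjusted over the list alone and 0 over all genes; the camera adjusted p was 0.00220 and the adjusted p 0.354 with an estimated correlation. Astrocyte markers were negative in 12 of 14 (median −0.037), with Aqp4 (−0.19 ± 0.0414) among 3 lower adjusted over the list alone and 0 over all genes, a camera adjusted p of 2.45e-04 and an adjusted p of 0.473 with an estimated correlation.

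The tests of this paragraph were chosen only after the result was seen. Mutant libraries fell into sets by Pttg1, which was chosen after its values were seen. In the 11 libraries under 1 CPM, Gm12663 averaged 2.753 ± 0.402 CPM and Ublcp1 25.88 ± 1.763, and in the 5 at 7.94 to 10.5 CPM they averaged 1.535 ± 0.345 and 30.35 ± 1.689 (exact permutation p 4.58e-04 each over 4368 splits, adjusted 0.0440). Thg1l averaged 9.498 and 7.345 CPM (exact p 0.00229, adjusted 0.1465), while the difference in Ccng1 did not pass (exact p 0.161). In male mutant CVS replicate 1, with Pttg1 at 18.73 CPM, Gm12663 had 0 counts, which allows up to 0.1559 CPM. Ublcp1 stood at 33.55 CPM in it, inside the control range of 31.91 to 41.87, but Ccng1 stood at 91.63 CPM, above the controls (62.45 to 79.99). Gpr83, Vgf and Prss23, like Ublcp1, were on the mutant side of the mean of its matched controls. This held in every mutant library, so it adds no support for the label of this one. Of 192 called genes other than Pttg1, 6 had an exact p under 0.05 between both sets and 2 passed when adjusted over the 192, both toward the controls. No explanation is given for the sets here.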
